A study of Mus musculus with 19 samples.

How the data were processed

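The series holds 19 libraries of hippocampus and cortex homogenate, each with a table of reads per gene and a table of reads per repeat subfamily. Per the labels' protocols, total RNA was extracted and paired-end libraries were made with a stranded total RNA kit, while the molecule label reads polyA RNA. Per the submitters' processing notes, Trimmomatic 0.36, STAR 2.5.2b and the builds mm10 and mm9 were used, with no role given for either build. The annotation release and the tool that counted repeats are not given in the sources used here. The deposited gene tables hold whole-number counts of reads that the authors did not normalize, for 53801 Ensembl gene IDs. Of these, 14 tables have 4 columns in the layout of STAR gene counts and 5 have 2 columns. In the 4-column tables the reads split between the strands at 49.9% to 50.1%, so the counts keep no strand, and the column without regard to strand was used. Genes with at most 5 reads in that column and over 100 by strand in every 4-column table numbered 223, and their highest count in the 2-column tables was 12, so the 2-column tables hold the same kind of count. The deposited repeat tables hold counts for 1067 subfamilies of 13 classes.

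Lines that name no gene stayed out of library sizes and tests. In the 14 tables that give them, reads on no gene were 6.57% to 13.4% of all reads, ambiguous reads 5.91% to 8.56%, multimapping reads 4.79% to 6.74% and unmapped reads 2.77% to 4.07%. Symbols, biotypes and coordinates came from GENCODE M21 on GRCm38, in which 53706 of the gene IDs have an entry and 95 do not. Clec7a is listed there as a polymorphic pseudogene. Because the counts keep no strand, the 42 called genes were compared with overlapping annotated genes: 11 share exonic bases with another gene, and in 4 (Tcf24, Mfrp, Xist and Asic4) over 10% of the exonic bases are shared.

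Groups and sex were taken from the labels, and replicate numbers only name libraries, in accession order, so no pairing was used. The labels call the samples separate mice. No pair of libraries within a group differed by as little as sampling noise: the smallest chi-square per degree of freedom was 5.59, over genes with at least 20 reads in the pair. The sex labels were compared with Xist and Ddx3y: the 12 female libraries had at least 521 CPM of Xist and at most 0.612 CPM of Ddx3y, and the 7 male libraries at most 3.17 CPM of Xist and at least 45.4 CPM of Ddx3y.

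Genes were tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood test with TMM scaling, the filterByExpr filter, sex as a covariate and Benjamini-Hochberg adjustment at 0.05. Each cohort was fitted with its own controls alone, and the contrast of the effects used all 19 libraries. CPM values in the text are scaled by TMM within the cohort. Repeat subfamilies were tested in the same way with the library size taken from the TMM-scaled gene counts, so that a shift of all repeats could show. Class totals in CPM of effective gene reads were compared by an exact two-sided permutation test of mean log2 values, adjusted over the classes. The smallest p it can give is 0.00303 in the poly(PR) cohort and 0.0286 in the poly(GR) cohort. The 51 gene lists were tested with camera (limma 3.58.1) at the preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation and with fry, whose main p tests whether a list's genes move on balance in one direction. A list score is the mean log2 CPM (prior count 2) of the members less the control mean. Of the list members 1 was not found among the genes, and 3 were found through a synonym.

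The groups, designs, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule named, per cohort, up to 10 genes per direction with the largest log2 fold change among called genes with mean log2 CPM of at least 1 and a gene-type symbol, up to 4 called members per list with the smallest adjusted p, and a fixed set whatever their values, made of the HP1, lamin, dsRNA editing and sensing and sex-check genes with Lbr, C9orf72, Gfap, Aif1 and Cdkn1a. For the difference of effects it named the 6 largest differences per direction among called genes, and for repeats up to 12 called subfamilies per cohort, and no gene or subfamily passed for these. Names that fall outside it, among them Tcf24, F5, the members called over a list alone and the genes named for the difference of effects, were chosen after their values were seen. The values of some called genes are not reported here. The fitting steps were tested on simulated counts in which 200 genes were changed, 100 by 1.5-fold and 100 by 2-fold: 45% and 75% were recovered in the poly(PR) design, 64% and 83% in the poly(GR) design, and 26% and 66% for the difference. Of 20 repeat subfamilies changed at each size, 60% and 85%, 45% and 100%, and 40% and 65% were recovered. Wrong calls were 3 of 124, 12 of 166 and 5 of 99 for genes, and 1 of 30, 1 of 30 and 2 of 23 for subfamilies. The simulated features varied independently, without structure shared between libraries, so recovery in the real data may differ.

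Alternatives were DESeq2 1.42.0, RLE size factors, no filter or a minimum of 1 CPM, no sex term, all libraries in one fit, glmTreat at 1.2-fold, 1 surrogate variable (sva 3.50.0), the format of the gene table as a batch term in the poly(GR) cohort, other scalings of repeats, and each library left out in turn. The median log2 fold change over all genes was 0.0062 with TMM and -0.0055 with RLE in the poly(PR) cohort, and 0.0032 and 0.00087 in the poly(GR) cohort. Alternatives added after the data were seen are named as such in the closing section. The format of the gene table could not be tested in the poly(PR) cohort, where all tables have 4 columns. Within the poly(GR) cohort, 3 control and 2 poly(GR) libraries have 2-column tables, and the fit with the format as a term called 25 genes. Fits within each format were added after the data were seen.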

Results

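RNA sequencing reads were counted per gene and per repeat subfamily in homogenates of hippocampus and cortex from 19 C57BL/6 mice aged 3 months. An adeno-associated virus (AAV1) had been injected into the cerebral ventricles of newborn pups. It carried GFP alone, or GFP joined to a dipeptide repeat protein that can be translated from the C9orf72 repeat expansion of amyotrophic lateral sclerosis and frontotemporal dementia. The repeat was 50 units of proline-arginine, poly(PR), or 100 units of glycine-arginine, poly(GR). The poly(PR) cohort held 7 poly(PR) mice (4 female, 3 male) and 4 GFP controls of the same harvest (3 female, 1 male). The poly(GR) cohort held 4 poly(GR) mice (3 female, 1 male) and 4 GFP controls of its own harvest (2 female, 2 male). Reads assigned to genes came to between 26934239 and 47648711 per library, and reads assigned to repeats to between 7020042 and 13011731. The study title places the series in a question about heterochromatin, the heterochromatin protein HP1α and the accumulation of double-stranded RNA (dsRNA).

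The comparison of poly(PR) with its controls asked which transcripts differ in brains that express poly(PR). Among the genes called higher with poly(PR) were Clec7a and Ccl6, found in microglia, Gfap of astrocytes and the complement gene C4b. Clec7a, which encodes the innate immune receptor dectin-1 found on activated microglia, rose 5.47-fold, from 0.751 ± 0.375 CPM (SD, n = 4) to 3.76 ± 1.16 CPM (SD, n = 7), with adjusted p = 0.0429 in edgeR's quasi-likelihood test. Gfap, the intermediate filament of astrocytes, rose 2.01-fold, from 244 ± 53.6 CPM (SD, n = 4) to 467 ± 90.1 CPM (SD, n = 7). C4b, a complement component, rose 2.07-fold, from 46.9 ± 10 CPM to 93.4 ± 20.8 CPM. The chemokine gene Ccl6 rose by 1.2 on the log2 scale (SE 0.17). Lag3, which encodes an inhibitory receptor of lymphocytes, rose by 1.04 (SE 0.15), and Hist1h1c, a linker histone gene, by 0.90 (SE 0.12). Among the 4 genes that fell were Dkk3, a secreted glycoprotein of the Dickkopf family (log2 fold change -0.55, SE 0.08), Gfra2, the neurturin co-receptor (-0.47, SE 0.07), and Zdhhc22, of the palmitoyltransferase family (-0.43, SE 0.06).

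In all, 11 of 19156 genes passed an adjusted p of 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 7 higher and 4 lower. An unadjusted p under 0.05 was found for 2863. In each of the 11, all 7 poly(PR) libraries lay beyond all 4 controls. The gene with the smallest adjusted p (0.00996) was Tcf24, a basic helix-loop-helix gene, which rose 5.93-fold from 0.388 ± 0.129 CPM (SD, n = 4) to 2.17 ± 0.550 CPM (SD, n = 7). It lies below the expression minimum of the naming rule and was chosen after its values were seen. On GRCm38, Tcf24 (ENSMUSG00000099032) spans chromosome 1, 9960163 to 9967932, and Clec7a (ENSMUSG00000079293) chromosome 6, 129461591 to 129472779. Gfap (ENSMUSG00000020932) spans chromosome 11, 102887336 to 102900912, C4b (ENSMUSG00000073418) chromosome 17, 34728380 to 34743882, and Hist1h1c (ENSMUSG00000036181) chromosome 13, 23738808 to 23740367. The annotation places E330040D14Rik on the other strand over 14.8% of the exonic bases of Tcf24, and the counts do not keep strand. C4b shares near-identical sequence with C4a, so its counts are uncertain to that extent. The count rested on the libraries used. Without poly(PR) replicate 6 it was 617 (289 higher, 328 lower, the 11 genes included). It was 0 without any of the 4 controls or without replicate 3 or 4, 1 without replicate 1 or 5, and 2 without replicate 2 or 7. It was 448 with DESeq2, 603 with 1 surrogate variable, 188 with all 19 libraries in one fit, and 69 without a filter on low counts. It was 4 without the sex term, 1 when a change beyond 1.2-fold was tested and 0 with the striatum score as a covariate.

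**Figure D1:**
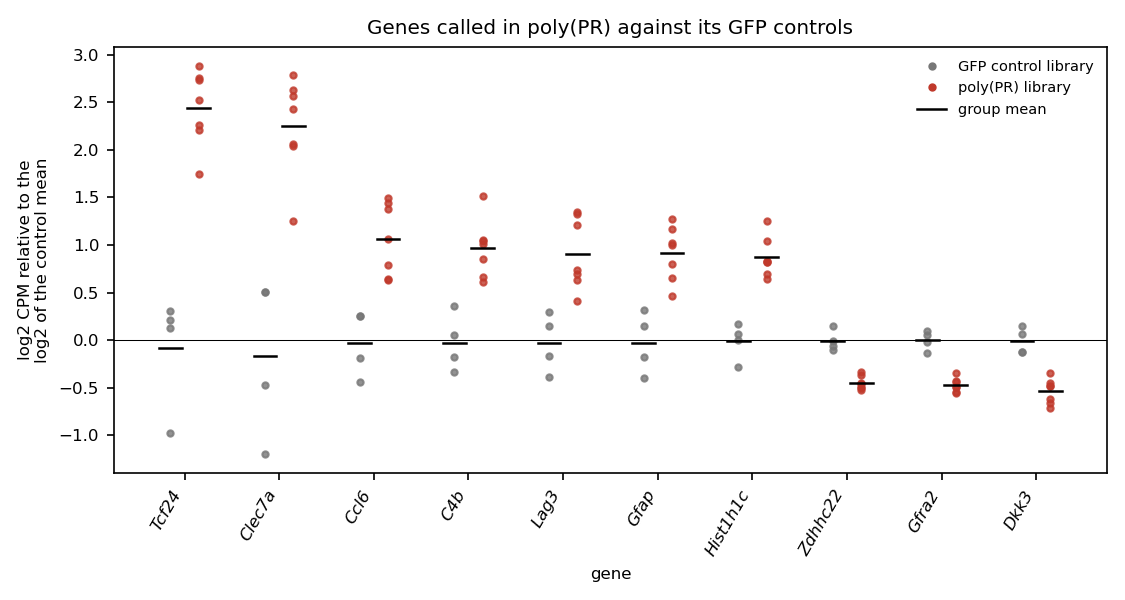
Log2 CPM relative to the log2 of the control mean (vertical axis) for 10 of the 11 genes called in the poly(PR) cohort (horizontal axis), 1 point per library, for the 4 GFP controls and the 7 poly(PR) mice, with group means as lines. Every poly(PR) library lies beyond all 4 controls in each of the genes shown.

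Among the gene lists fixed before the data were examined, the disease-associated microglia list had the smallest p by camera with its preset correlation in poly(PR). Of its 22 measured genes, 15 rose adjusted over the list alone and 2, Clec7a and Ccl6, over all genes tested. Cst7, a cysteine protease inhibitor, rose by 2.21 on the log2 scale (SE 0.41) and the integrin gene Itgax by 2.00 (SE 0.40), as did the galectin gene Lgals3 by 1.23 (SE 0.27) and the lipid-sensing receptor gene Trem2 by 0.64 (SE 0.13), each adjusted over the list alone. The list score, the mean log2 CPM of the members relative to the control mean, was 0.617 ± 0.190 (SD, n = 7), higher than every control in 7 of 7 libraries (exact two-sided permutation test, p = 0.00303, adjusted p = 0.0386 over 51 lists). The camera test with its preset correlation gave adjusted p = 4.55e-19, against adjusted p = 0.116 with an estimated correlation. In the wider microglia list 9 of 20 genes rose and 1, Tmem119, a marker of resting microglia, fell, adjusted over the list alone, and 0 passed over all genes. By camera this list had adjusted p = 8.00e-07, and adjusted p = 0.174 with an estimated correlation. Cd68, C1qa, C1qb and Tyrobp were among the 9.

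Inflammatory, complement and reactive astrocyte lists were also called higher in poly(PR) by camera with its preset correlation. In the inflammatory cytokine and NF-kB list 7 of 18 genes rose adjusted over the list alone, among them the chemokine genes Ccl3 (log2 fold change 1.72, SE 0.34) and Ccl4 (1.79, SE 0.37), and the receptor gene Tlr2 (1.09, SE 0.25). Nfkbia, which encodes an NF-kB inhibitor, fell (-0.58, SE 0.10), and 0 of the list passed over all genes. Its camera adjusted p was 6.94e-05, against adjusted p = 0.145 with an estimated correlation. In the complement list 6 of 16 genes rose adjusted over the list alone and 1, C4b, over all genes (camera adjusted p = 0.00746, adjusted p = 0.356 with an estimated correlation). Of the 16, 9 had log2 fold changes above 0 and 7 below, and the score did not pass (exact permutation p = 0.239, adjusted p = 0.435). In the pan-reactive astrocyte list 6 of 12 rose adjusted over the list alone and 1, Gfap, over all genes, with Serpina3n (0.38, SE 0.10) and Vim (0.31, SE 0.10) among the 6. Camera gave it adjusted p = 0.0011, and adjusted p = 0.145 with an estimated correlation. In the histone list 5 of 16 rose adjusted over the list alone and 1, Hist1h1c, over all genes (camera adjusted p = 3.48e-05, adjusted p = 0.191 with an estimated correlation). Of the interferon-stimulated genes 1 of 37, Mx1 (0.88, SE 0.20), rose adjusted over the list alone and 0 over all genes (camera adjusted p = 0.000139, adjusted p = 0.49 with an estimated correlation).

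Lists of neuronal activity and synaptic genes were called lower in poly(PR) by camera with its preset correlation. Of 21 immediate early genes, which neurons transcribe within minutes of stimulation, 13 fell adjusted over the list alone and 0 over all genes. Egr2 changed by -1.34 on the log2 scale (SE 0.28), Fos by -1.16 (SE 0.27), Arc by -1.09 (SE 0.31) and Npas4 by -0.86 (SE 0.23). The camera adjusted p was 1.49e-16, against adjusted p = 0.145 with an estimated correlation. The list score was -0.637 ± 0.236 (SD, n = 7), below every control in 6 of 7 libraries (exact permutation p = 0.00606, adjusted p = 0.0386). In the synaptic vesicle list 11 of 21 genes fell adjusted over the list alone and 0 over all genes, among them the SNARE gene Snap25 (-0.27, SE 0.06) and the vesicle protein gene Sv2b (-0.52, SE 0.16). Its score lay below all controls in 7 of 7 libraries (exact permutation p = 0.00303, adjusted p = 0.0386). By camera it had adjusted p = 1.37e-07, and adjusted p = 0.114 with an estimated correlation. In the excitatory neuron list 8 of 12 fell adjusted over the list alone and 0 over all genes, including the transcription factor gene Neurod6 (-0.53, SE 0.15). For that list camera gave adjusted p = 1.35e-06, and adjusted p = 0.114 with an estimated correlation. The pan-neuronal marker list was lower as well: 5 of 15 fell adjusted over the list alone and 0 over all genes, among them Nefm (-0.34, SE 0.10) and Rbfox3 (-0.18, SE 0.06). Its score was -0.161 ± 0.0648 (SD, n = 7), below every control in 7 of 7 libraries (exact permutation p = 0.00303, adjusted p = 0.0386), with camera adjusted p = 7.92e-05 and adjusted p = 0.174 with an estimated correlation.

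A list of genes of the striatum, a region that the homogenate labels do not name, was called higher in poly(PR) by the same test. Of its 14 genes 11 rose adjusted over the list alone and 0 over all genes. Among them were the adenosine receptor gene Adora2a at 0.74 (SE 0.13), the enkephalin precursor gene Penk at 0.66 (SE 0.11) and the dopamine receptor gene Drd2 at 0.59 (SE 0.13). Its score was 0.390 ± 0.207 (SD, n = 7), above every control in 7 of 7 libraries (exact permutation p = 0.00606, adjusted p = 0.0386). Camera gave adjusted p = 6.01e-15, and adjusted p = 0.145 with an estimated correlation. Dentate gyrus genes had a score of -0.307 ± 0.167 (SD, n = 7), below every control in 7 of 7 libraries (exact permutation p = 0.00909, adjusted p = 0.0421). Of its genes 3 of 11, Tdo2, Dsp and Trpc6, fell adjusted over the list alone and 0 over all genes (camera adjusted p = 8.62e-05, adjusted p = 0.169 with an estimated correlation). Hippocampal CA field, upper-layer cortex and thalamus lists were also called lower by camera (adjusted p = 0.0033, 0.0094 and 0.00075). With an estimated correlation their adjusted p was 0.205, 0.169 and 0.238. Their scores did not pass (exact permutation test, adjusted p = 0.195, 0.0514 and 0.351). Whether differences in the dissected tissue bear on these and the neuronal lists was not tested. In all, camera with its preset correlation called 23 of 51 lists (11 higher, 12 lower), and 0 with an estimated correlation (13 lists at an unadjusted p under 0.05, 15 by fry). The exact permutation test of the scores, added after the data were seen, called 11.

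**Figure D2:**
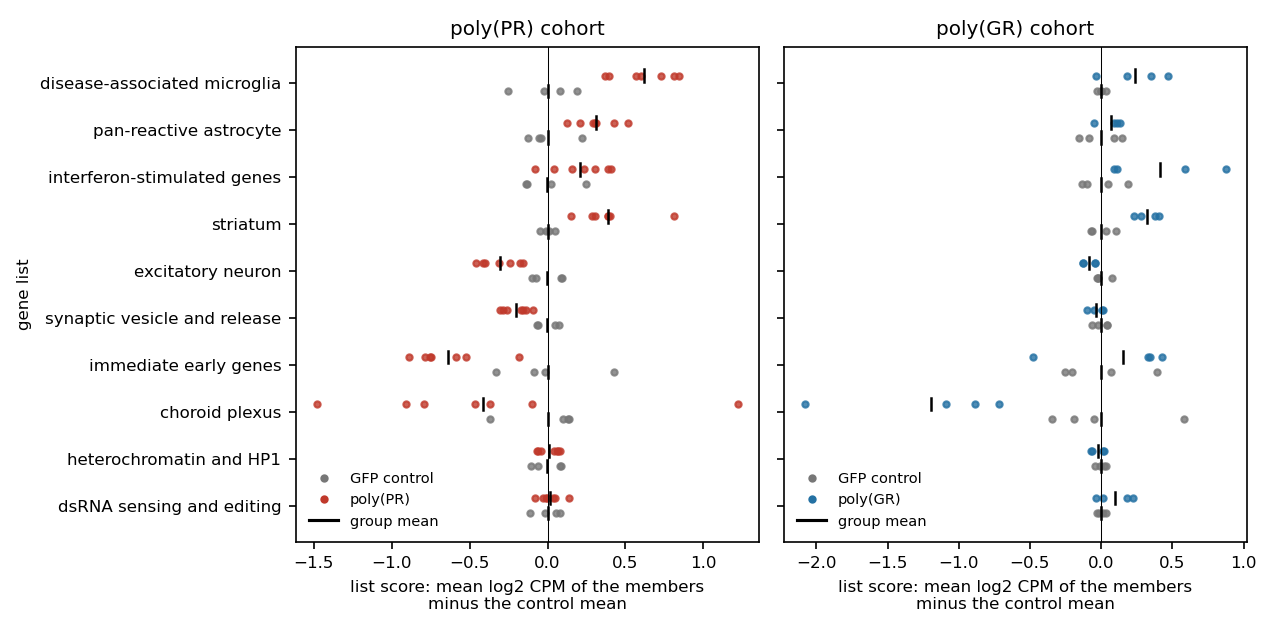
Scores of selected gene lists, the mean log2 CPM of the members minus the control mean, 1 point per library, for GFP controls and treated mice of the poly(PR) cohort (left) and the poly(GR) cohort (right), with a bar at each group mean. The disease-associated microglia score lies above every control in 7 of 7 poly(PR) libraries, and the choroid plexus score lies below every control in 4 of 4 poly(GR) libraries.

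Transcripts of heterochromatin, nuclear lamina and dsRNA-sensing proteins, the components that the study title points to, were measured next. In poly(PR), Cbx5, which encodes HP1α, was at 204 ± 37.5 CPM (SD, n = 7) against 232 ± 42.7 CPM (SD, n = 4) in controls (log2 fold change -0.21, SE 0.15, adjusted p = 0.457). The other HP1 genes, Cbx1 and Cbx3, had log2 fold changes of -0.11 (SE 0.08) and -0.23 (SE 0.11, adjusted p = 0.344). The lamin genes Lmna, Lmnb1 and Lmnb2 had log2 fold changes of -0.03 (SE 0.09), 0.04 (SE 0.10) and 0.09 (SE 0.12). For the lamin B receptor gene Lbr it was -0.22 (SE 0.11), and none of these passed the threshold. Nor did the dsRNA editing and sensing genes Adar (-0.13, SE 0.09), Dhx9 (-0.32, SE 0.16), Eif2ak2 (0.13, SE 0.10) and Ifih1 (0.08, SE 0.17) pass it. C9orf72 (-0.13, SE 0.10) and Cdkn1a (0.02, SE 0.17) did not either, nor did the microglial marker gene Aif1 (0.47, SE 0.16, adjusted p = 0.253, which was 0.0441 without poly(PR) replicate 6). The lists around these genes were not called by camera. Its adjusted p was 0.838 for heterochromatin and HP1 (0 of 31 genes adjusted over the list alone and 0 over all genes), 0.594 for nuclear lamina and envelope (0 of 18) and 0.594 for dsRNA sensing and editing (0 of 22), with 0 genes by edgeR at the adjusted threshold in each.

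The comparison of poly(GR) with its own controls asked the same of the other arginine-containing repeat protein. C4b rose 2.67-fold with poly(GR), from 27.8 ± 6.43 CPM (SD, n = 4) to 67.2 ± 20.4 CPM (SD, n = 4), with adjusted p = 0.00591. Zc3hav1, which encodes the antiviral zinc finger protein ZAP, rose 1.95-fold, from 5.82 ± 0.336 CPM (SD, n = 4) to 11.2 ± 1.68 CPM (SD, n = 4). The collagen gene Col6a1 rose by 0.66 on the log2 scale (SE 0.08), the transcription factor gene Rreb1 by 0.55 (SE 0.07), Serpina9 by 0.56 (SE 0.09) and the paraspeckle RNA Neat1 by 0.48 (SE 0.06). Genes of the choroid plexus, the epithelium that makes cerebrospinal fluid, were lower. The folate receptor gene Folr1 changed by -2.15 (SE 0.26), Tmem72 by -2.07 (SE 0.31), the coagulation factor gene F5 by -1.87 (SE 0.31) and Kl, which encodes klotho, by -1.01 (SE 0.16). Folr1, Tmem72 and F5 were low in expression, at means of 1.88, 2.66 and 2.80 CPM in controls and 0.518, 0.768 and 0.882 CPM in poly(GR). Kl was at 12.2 and 6.44 CPM.

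Over all genes, 32 of 18511 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 15 higher and 17 lower. There were 2124 with an unadjusted p under 0.05. The striatal genes Rgs9 (log2 fold change 0.43, SE 0.05), Adora2a (0.50, SE 0.07), Syndig1l (0.43, SE 0.06) and Drd1 (0.28, SE 0.05) were among those that rose, as was the retinoid receptor gene Rxrg (0.43, SE 0.06). Among those that fell were the kinase gene Sgk1, which responds to glucocorticoids (-0.77, SE 0.11), the lipid droplet gene Plin4 (-0.99, SE 0.17), Nfkbia (-0.49, SE 0.09), Neurod6 (-0.37, SE 0.06) and Enpp2, which encodes autotaxin (-0.39, SE 0.06). Xist also fell (-0.65, SE 0.09, adjusted p = 0.0145), and its call rests on female libraries. Controls 1 and 2 were at 926 and 934 CPM, and poly(GR) replicates 1 to 3 at 556, 523 and 593 CPM. On GRCm38, Folr1 (ENSMUSG00000001827) spans chromosome 7, 101858331 to 101870788, Zc3hav1 (ENSMUSG00000029826) chromosome 6, 38305286 to 38354603, and Kl (ENSMUSG00000058488) chromosome 5, 150952607 to 150993817. The count was 0 without control replicate 1, 18 without control 2 and 20 without control 4. It was 111 (74 higher, 37 lower, 21 of the 32 included) without poly(GR) replicate 4, the 1 male of its group. With the sex term that fit compares the 3 female poly(GR) libraries with controls 1 and 2, which had rRNA shares of repeat counts of 59.5% and 49.1%. DESeq2 called 155, and edgeR 522 without a filter. Within the 5 libraries with 2-column gene tables (3 controls, 2 poly(GR)) 35 genes were called, 14 of the 32 included. Within the 3 with 4-column tables (1 control, 2 poly(GR)) 93 were called, 10 of the 32 included, where the lone control is assumed to vary like the other group. The count was 8 without the sex term, 6 for a change beyond 1.2-fold, 1 with all 19 libraries in one fit and 0 with the choroid plexus score as a covariate.

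**Figure D3:**
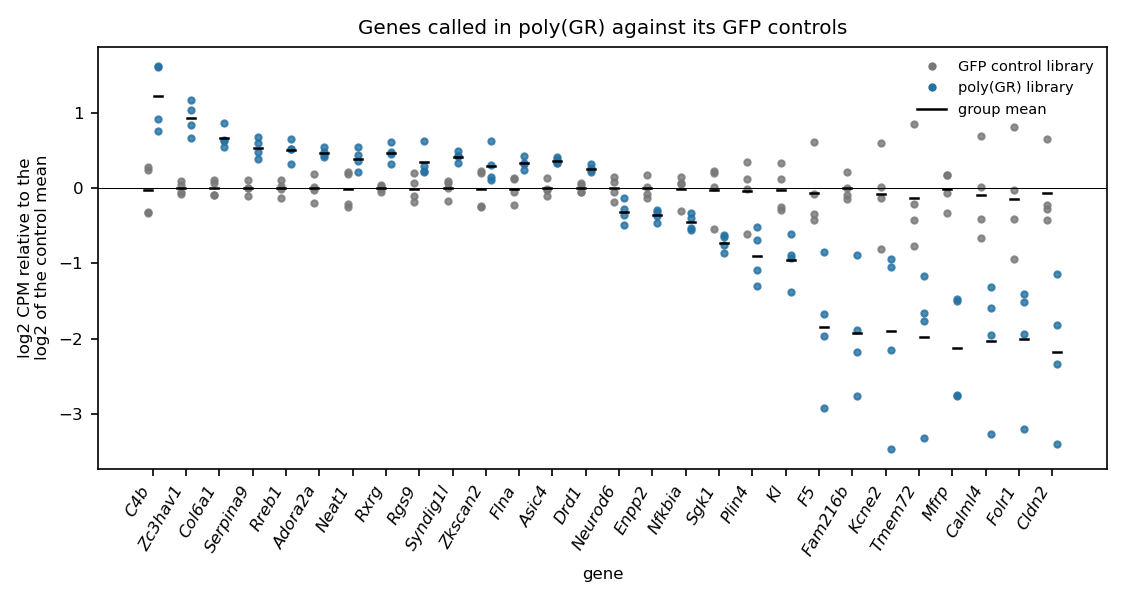
Log2 CPM relative to the log2 of the control mean (vertical axis) for genes called in the poly(GR) cohort (horizontal axis; Xist, genes with clone-type symbols and some others are left out), 1 point per library, for the 4 GFP controls and the 4 poly(GR) mice, with group means as lines. C4b lies above and Folr1 below every control in 4 of 4 poly(GR) libraries.

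By list, poly(GR) brains showed lower choroid plexus genes and higher striatal genes. Of 15 choroid plexus genes 14 fell adjusted over the list alone and 6 over all genes, with Ttr, the abundant transthyretin gene, at -2.73 (SE 0.64). The camera adjusted p was 7.60e-35, against adjusted p = 0.119 with an estimated correlation. In poly(PR) 14 of the 15 had log2 fold changes below 0, with 0 called adjusted over the list alone and 0 over all genes (camera adjusted p = 0.021, adjusted p = 0.694 with an estimated correlation, score -0.413 ± 0.846, SD, n = 7, exact permutation p = 0.391). Of 10 ependymal genes, of the cells that line the ventricles, 9 had log2 fold changes below 0 in poly(GR), and 2, Dynlrb2 (-1.33, SE 0.39) and Ccdc153 (-1.36, SE 0.36), fell adjusted over the list alone and 0 over all genes. That list had camera adjusted p = 4.85e-05, and adjusted p = 0.494 with an estimated correlation. Its score lay below every control in 3 of 4 libraries (exact permutation p = 0.0857, adjusted p = 0.437). Of 14 striatal genes 14 rose adjusted over the list alone and 5 over all genes (camera adjusted p = 9.42e-32, adjusted p = 0.065 with an estimated correlation, fry adjusted p = 0.0205). The excitatory neuron score lay below and the inhibitory neuron score above every control in 4 of 4 libraries (exact permutation p = 0.0286, adjusted p = 0.208 for each). The interferon and antigen presentation lists were called higher in poly(GR) by camera with its preset correlation alone. Of 37 interferon-stimulated genes 9 rose adjusted over the list alone and 0 over all genes, among them the oligoadenylate synthetase family genes Oasl2 (1.46, SE 0.33) and Oas1a (1.01, SE 0.23), and Ifit1 (0.83, SE 0.26). For them camera gave adjusted p = 6.68e-16, and adjusted p = 0.494 with an estimated correlation. The interferon list scores of the 4 poly(GR) libraries were 0.873, 0.110, 0.0908 and 0.588, and those of the controls -0.0976, 0.186, -0.136 and 0.0476 (exact permutation p = 0.114, adjusted p = 0.485). In the MHC class I list 9 of 16 rose adjusted over the list alone and 0 over all genes, including H2-D1 (0.55, SE 0.11), H2-K1 (0.48, SE 0.12) and Tap1 (0.70, SE 0.16). This list had camera adjusted p = 5.65e-11, and adjusted p = 0.494 with an estimated correlation. Its score lay above every control in 4 of 4 libraries (exact permutation p = 0.0286, adjusted p = 0.208). In poly(PR) 15 of its 16 genes had log2 fold changes above 0 (camera adjusted p = 0.000715, adjusted p = 0.525 with an estimated correlation). There the score did not pass (exact permutation p = 0.173, adjusted p = 0.351). The H2 genes are a family of near-identical copies whose counts are uncertain.

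The disease-associated microglia list was called higher by the preset camera test in poly(GR) as well, but its score did not pass (0.241 ± 0.219, SD, n = 4, above every control in 3 of 4 libraries and below every control in 1, exact permutation p = 0.143, adjusted p = 0.486). Of the disease-associated microglia list 6 of 22 rose adjusted over the list alone and 0 over all genes, including Clec7a (1.07, SE 0.29), Cst7 (1.65, SE 0.47) and Apoe (0.31, SE 0.09) (camera adjusted p = 8.06e-08, adjusted p = 0.494 with an estimated correlation). In the wider microglia list 9 of 20 rose and 1 fell adjusted over the list alone and 0 over all genes (camera adjusted p = 6.49e-06, adjusted p = 0.494 with an estimated correlation). Its score lay above every control in 4 of 4 libraries (exact permutation p = 0.0286, adjusted p = 0.208). In the complement list 6 of 16 rose and 1 fell adjusted over the list alone, and 1, C4b, rose over all genes (camera adjusted p = 2.34e-06, adjusted p = 0.494 with an estimated correlation). Gfap was at 217 ± 27.9 CPM (SD, n = 4) against 203 ± 29.5 CPM (SD, n = 4) (log2 fold change 0.18, SE 0.06, adjusted p = 0.327). Cbx5 was at 267 ± 12.7 CPM (SD, n = 4) against 282 ± 13.2 CPM (SD, n = 4) (-0.08, SE 0.06, adjusted p = 0.636). The log2 fold changes of Cbx1 (-0.06, SE 0.05), Cbx3 (-0.10, SE 0.07), Lmna (-0.01, SE 0.06), Lmnb1 (-0.01, SE 0.08), Lmnb2 (0.05, SE 0.06) and Lbr (0.06, SE 0.10) did not pass either. Nor did those of Adar (0.01, SE 0.05), Dhx9 (-0.01, SE 0.06), Ifih1 (0.18, SE 0.14), C9orf72 (-0.10, SE 0.06), Cdkn1a (-0.08, SE 0.09) and Aif1 (0.09, SE 0.11). Eif2ak2 was at 0.32 (SE 0.14, adjusted p = 0.422), above every control in 4 of 4 libraries. The heterochromatin and HP1 list (0 of 31 genes adjusted over the list alone, camera adjusted p = 0.846) and the nuclear lamina list (1 of 18 higher adjusted over the list alone, camera adjusted p = 0.744) were not called, with 0 genes of either over all genes. The dsRNA sensing list was called higher by camera (adjusted p = 0.0392, adjusted p = 0.544 with an estimated correlation), with 1 of 22 genes, Oas1a, higher adjusted over the list alone and 0 over all genes. In all, camera called 20 of 51 lists (11 higher, 9 lower), and 0 with an estimated correlation (3 at an unadjusted p under 0.05, 1 by fry). The exact permutation test of the scores called 0 (lowest adjusted p = 0.208, 7 at an unadjusted p under 0.05), where the smallest p that 4 against 4 libraries can give is 0.0286.

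Whether the effects of poly(PR) and poly(GR) differ was tested as a contrast over all 19 libraries. Gfap rose 2.01-fold in poly(PR) and was 1.13-fold higher in poly(GR) without passing the test. The difference of its log2 fold changes was 0.87 (SE 0.23, adjusted p = 0.786). In edgeR's test 0 of 19863 genes differed at an adjusted p of 0.05, 1066 had an unadjusted p under 0.05, and DESeq2 called 4. The smallest adjusted p was that of Tcf24 (difference 2.78, SE 0.42, adjusted p = 0.0573), named after its values were seen. It passed the threshold in each of 5 fits that left out 1 library, poly(PR) replicate 1, 5, 6 or 7 or poly(GR) replicate 4. Immediate early genes had a median difference of -0.65, with 21 of 21 below 0, and the median for ribosomal protein genes was 0.29, with 53 of 53 above 0. Camera, applied to this contrast after the data were seen, called 26 lists, and 0 with an estimated correlation (lowest adjusted p = 0.0993, 9 at an unadjusted p under 0.05).

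C4b was called higher in both cohorts, which used separate controls. It was the 1 shared call among 18200 genes tested in both (Fisher's exact test p = 0.00576 for higher calls, 0.00577 shared calls expected by chance), and no lower call was shared (0, Fisher's exact test p = 1). Of the 32 poly(GR) calls 32 had the same sign in poly(PR), and of the 11 poly(PR) calls 9 had the same sign in poly(GR). Across genes, which are not independent replicates, the log2 fold changes correlated with Pearson r = 0.323 and Spearman rho = 0.312. The number of shared calls was 10 at an adjusted p of 0.1 and 38 with DESeq2. It was 12 without poly(PR) replicate 6, 2 without poly(GR) replicate 3, and 0 without poly(GR) control 1 or without any of the other 10 libraries of the poly(PR) cohort.

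Repeat transcripts were compared because heterochromatin silences repetitive DNA. In poly(PR), totals of long interspersed (LINE), short interspersed (SINE), long terminal repeat (LTR) and satellite transcripts differed from controls by less than the test could tell from the spread between libraries. LINE counts were 48560 ± 5691 CPM of effective gene reads (SD, n = 7) in poly(PR) and 48410 ± 4068 (SD, n = 4) in controls. Satellite counts were 2530 ± 179 (SD, n = 7) and 2640 ± 270 (SD, n = 4). The total over transposable elements differed by 0.0061 on the log2 scale (95% permutation interval -0.12 to 0.15, exact two-sided permutation test, p = 0.921), and in poly(GR) by -0.04 (-0.22 to 0.24, exact permutation p = 0.6). By subfamily, edgeR called 0 of 975 in poly(PR) (28 at an unadjusted p under 0.05) and 0 of 955 in poly(GR) (20 at an unadjusted p under 0.05). It called 0 of 982 for the difference of the effects (9 at an unadjusted p under 0.05). DESeq2 called 0 in both cohorts. Without poly(PR) replicate 6 the count in poly(PR) was 1, and without poly(GR) replicate 4 the count in poly(GR) was 18 (1 higher, 17 lower), from female poly(GR) libraries against controls 1 and 2.

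The repeat class with the lowest p in poly(PR) was ribosomal RNA. Its total was 117900 ± 17830 CPM of effective gene reads (SD, n = 7) against 158500 ± 19950 (SD, n = 4), which did not pass the adjustment over 13 classes (exact permutation p = 0.0152, adjusted p = 0.197). As a share of all repeat counts, rRNA was lower in poly(PR), 36.5% ± 3.08 (SD, n = 7) against 43.7% ± 2.71 (SD, n = 4) (exact permutation p = 0.00909, adjusted p = 0.0364 over 8 library measures), and lay below every control in 6 of 7 libraries. The share of reads that fell on more than 1 gene was also lower in poly(PR), 7.28% ± 0.480 (SD, n = 7) against 8.15% ± 0.381 (SD, n = 4) (exact permutation p = 0.0152, adjusted p = 0.0404). The number of genes with a read was higher, 29360 ± 333 against 28640 ± 324 (exact permutation p = 0.00606, adjusted p = 0.0364). Whether these differences between libraries bear on the gene calls in poly(PR) was not tested. In poly(GR) the rRNA share was 26.9% ± 3.24 (SD, n = 4) against 39.2% ± 17.9 (SD, n = 4) (exact permutation p = 0.371, adjusted p = 0.533). The 2 female controls were at 59.5% and 49.1% and the 2 male controls at 22.9% and 25.4%. When classes were scaled to all repeat counts, 7 of 13 classes passed in poly(PR), 6 higher and 1, rRNA, lower. Scaled to repeat counts without rRNA, a scaling chosen after the data were seen, the exact permutation test called 0 (0 at an unadjusted p under 0.05, lowest adjusted p = 0.676). As a share of all repeat counts, the transposable element total was higher in poly(PR) by 0.17 on the log2 scale (exact permutation p = 0.00909). Without rRNA in the scaling, the difference was 0.000761 (exact permutation p = 0.488). These elements made up nearly all of the repeat counts left, so that this share could hardly move.

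**Figure D4:**
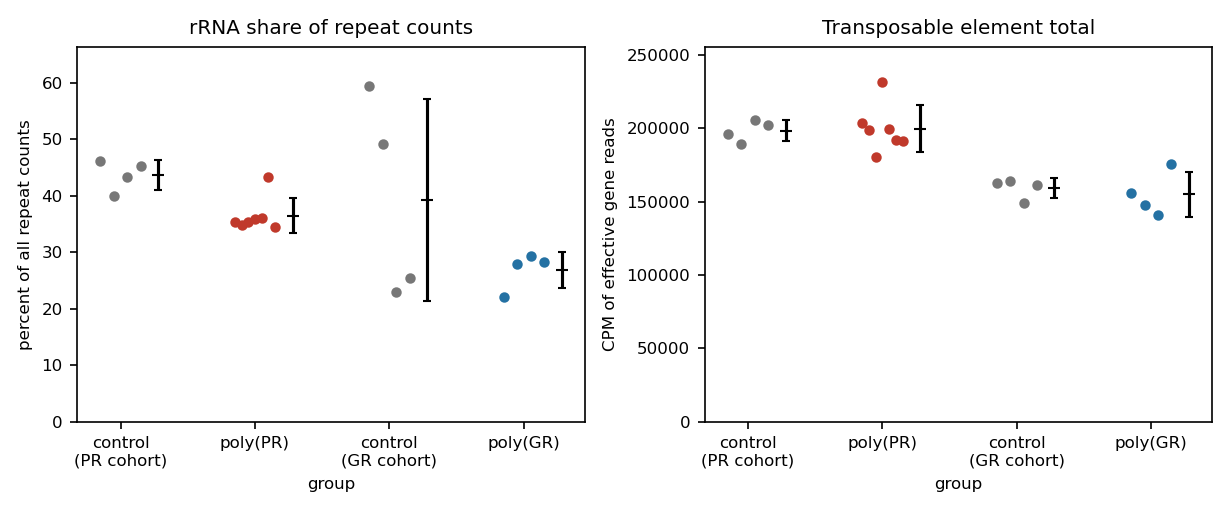
Share of rRNA in all repeat counts in percent (left) and transposable element totals in CPM of effective gene reads (right), 1 point per library in each of the 4 groups, with mean and SD. The rRNA share averages 36.5% in poly(PR) and 43.7% in its controls, while the transposable element totals overlap.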

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

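The tests of explanations for transposable element shares and for striatal and choroid plexus genes, and 2 of the 3 tests of a mislabelled control, were chosen only after the result was seen; the position of poly(PR) replicate 6 had its prediction written before.

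Poly(PR) replicate 6 stood apart in its rRNA share of repeat counts, 43.3% against 34.4% to 36.1% in the other poly(PR) libraries, with a gap of 0.815 of the group's range. Poly(PR) replicate 4 stood apart in C4b (134 CPM against 71.9 to 97.2, gap 0.594) and in SINE totals (113200 CPM of effective gene reads against 91280 to 100500, gap 0.579). It did so too in the class named RNA (152 against 59.8 to 84.9, gap 0.727) and in the class named Other (748 against 551 to 611, gap 0.698). Poly(GR) replicate 4, the male of its group, stood apart in Rgs9 (155 CPM against 117 to 123, gap 0.836). It did so in scRNA totals (637 against 468 to 483, gap 0.914) and in the class RNA (82.6 against 44.1 to 48.8, gap 0.879). Control replicate 1 of the poly(GR) cohort stood apart in Cldn2 (2.38 CPM against 1.13 to 1.3, gap 0.865). Control replicate 3 of that cohort did so in LTR totals (31580 against 34190 to 34630, gap 0.856). Control replicate 3 of the poly(PR) cohort stood apart in SINE totals (103700 against 95900 to 96720, gap 0.895). Of 198 groups of values tested in this way 11 passed, and chance alone gives 9.9.

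Transposable elements were a larger share of repeat counts in poly(PR), by 0.17 on the log2 scale, and under scaling to gene reads no difference passed the test. A candidate explanation is the rRNA in the denominator, since the log2 difference was 0.00609 in CPM of effective gene reads, though it was 0.0772 (exact permutation p = 0.258) when scaled to total gene reads without TMM. Higher transposable element RNA in poly(PR) cannot be told apart from it: the upper end of the 95% permutation interval was 0.151 with TMM, below the difference of the share, and 0.222 without TMM, above it. Uneven removal of rRNA between libraries stays open as the source of the rRNA difference, since the rRNA share differed 2.59-fold between the highest and the lowest library inside the poly(GR) controls alone. A change of rRNA itself through poly(PR) was not tested.

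Poly(PR) replicate 6 lay between the groups: over the 200 genes with the smallest p in a fit without it, its median position was 0.418, with 0 at the control mean and 1 at the poly(PR) mean, and the other poly(PR) libraries, each left out in the same way, lay at 0.821 to 1.17. A mislabelled control was tested 3 times and no test argues against it: 0.418 is below the 0.539 of left-out control replicate 1, replicate 6 lay beyond all controls at 16 of the 20 leading genes where that control lay beyond the other 3 at 20, and replicate 6 lay nearer the poly(PR) mean at 13 of the 20, above the 12 of the highest control and below the 15 that would have excluded the explanation. The last of these decides nothing, so that a mislabelled control stays open. A weaker response in this animal cannot be told apart from it, because a control reached 0.539. Replicate 6 had 2.85 CPM of Tcf24, the highest of the poly(PR) libraries, and 3.09 CPM of Clec7a, against at most 0.481 and 1.07 CPM in the controls. It lay beyond all controls in each of the 11 called genes. All 11 were also among the 617 genes called without it, but its own values helped to narrow those to the 11.

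Lists of striatal genes were called higher in both cohorts and of choroid plexus genes lower in both by camera with its preset correlation; with an estimated correlation the striatal lists had adjusted p = 0.145 in poly(PR) and 0.065 in poly(GR), and the choroid plexus lists 0.694 and 0.119. More striatum in the treated dissections cannot be told apart from a response of these genes: inside groups they correlated at a mean of 0.486 in poly(PR) and 0.225 in poly(GR), but interferon (0.353 and 0.64) and immediate early genes (0.422 and 0.601) did so too, as any list with a shared response would. Uneven carry-over of choroid plexus stays open for its genes. Their score spanned 2.7 inside the poly(PR) group, more than the change of -1.19 in poly(GR). That group was itself treated. Inside the controls the score spanned less than that change, 0.503 in the poly(PR) cohort and 0.927 in the poly(GR) cohort. The spans therefore do not decide on carry-over. Lower expression of choroid plexus genes through poly(GR) cannot be told apart from it, as the tables hold no measure of the amount of this tissue and the exact permutation p of 0.0286 is the smallest that the design gives. With the striatum score as a covariate edgeR called 0 genes in poly(PR) (2705 at an unadjusted p under 0.05), where Clec7a went from 2.45 (SE 0.32) to 2.16 (SE 0.49), and with the choroid plexus score 0 in poly(GR) (825 at an unadjusted p under 0.05), where genes outside that list such as Rreb1 (0.55, SE 0.07, to 0.62, SE 0.18) and Sgk1 (-0.77, SE 0.11, to -0.89, SE 0.29) lost the call through a wider error, while members such as Folr1 shrink by construction.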

How the results depend on the processing

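The robust fit, the striatum and choroid plexus covariates, the fits without poly(GR) controls 1 and 2 together, the fits within 1 table format, the exact test of list scores, repeat scaling without rRNA, the surrogate variable for lists, the table format as a term for lists and repeats, and the list test of the difference were chosen after the data were seen; the other settings were planned. No paired analysis was possible because replicate numbers follow accession order alone. RLE size factors, the stricter filter and the robust fit left the counts of called genes within 1.5 times: 11, 15 and 11 in poly(PR), 32, 27 and 35 in poly(GR). Genes called in poly(PR) were 4 without the sex term, 448 (203 higher, 245 lower) with DESeq2, 69 without a filter, 188 with all 19 libraries, 1 with glmTreat, 603 (215 higher, 388 lower) with 1 surrogate variable and 0 with the striatum score. In poly(GR) they were 8, 155 (95 higher, 60 lower), 522 (376 higher, 146 lower), 1 and 6 with the first 5 of these, 41 with 1 surrogate variable, 0 with the choroid plexus score, 2 without controls 1 and 2 (the female controls, so that with the sex term the fit rests on poly(GR) replicate 4), 35 within the 2-column tables and 93 within the 4-column tables (1 control). The last and the third last say little, as 1 library makes an arm. For the difference of effects DESeq2 called 4 and the unfiltered fit 1. Shared calls were 10 at an adjusted p of 0.1 and 38 with DESeq2. Lists called in poly(PR) fell from 23 to 0 with an estimated correlation, 15 by fry and 11 by the exact test of scores. In poly(GR) they fell from 20 to 0, 1 and 0, and for the difference from 26 to 0. Classes called in poly(PR) were 7 when scaled to all repeat counts. Scaled to repeat counts without rRNA they were 0. The causes were not tested, except that leaving libraries out lowers the number of samples.

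With each library left out in turn, genes called ranged from 0 to 617 in poly(PR), 0 to 111 in poly(GR) and 0 to 3 for the difference; subfamilies from 0 to 1, 0 to 18 and 0 to 0. Lists ranged from 21 to 26, 17 to 26 and 22 to 27, shared calls from 0 to 12, the correlation across genes from 0.27 to 0.345, and class totals called were 0 throughout. Of 1186 such fold changes of named genes 963 kept their direction and their side of the threshold, 215 lost the call in the same direction, 8 gained it and 0 changed direction past the threshold. The highest count in poly(PR) was without replicate 6 and in poly(GR) without replicate 4, its lone male, which leaves female libraries against controls 1 and 2.

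Signs differed in 10 cases. With the choroid plexus score Tmem72 was at 0.046, Kl at 0.053 and F5 at 0.037; without poly(GR) controls 1 and 2, Xist was at 0.0064, a comparison of males by construction, and the homeostatic astrocyte and pericyte lists pointed down (adjusted p = 0.208 and 0.887). Within the 4-column tables the interferon list pointed down and the heat shock and chaperone list up (adjusted p = 0.49 and 0.846), where the lone control is the one with the highest interferon score. These 5 cases rest on 1 library in an arm and are no evidence of a turn. With 1 surrogate variable the ribosomal protein list pointed down in poly(PR) (adjusted p = 0.456), and as a share of repeat counts the class Other was higher by 0.16. The groups overlapped in depth, with exact permutation p = 0.164 for the gene totals of the poly(PR) cohort and 0.4 for those of the poly(GR) cohort. Low genes such as Tcf24, at 0.388 CPM in controls, rest on few reads.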

Other observations

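The permutation tests of list scores, the interaction of treatment and sex, and the list test of the difference of effects were chosen only after the data were seen; the counts over other splits were planned.

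Further lists moved in part. In poly(PR), the apoptosis list had a score of 0.149 ± 0.0413 (SD, n = 7), above every control in 6 of 7 libraries (exact permutation p = 0.00606, adjusted p = 0.0386). Of its genes 3 of 22, the inflammatory caspase gene Casp4 (log2 fold change 0.95, SE 0.27), the adaptor gene Fadd (0.49, SE 0.14) and the TNF receptor gene Tnfrsf1a (0.38, SE 0.11), rose adjusted over the list alone and 0 over all genes. Its camera adjusted p was 0.0514, and adjusted p = 0.174 with an estimated correlation. Of 5 lymphocyte genes measured, Cd4 (0.49, SE 0.14), Cd79b (1.04, SE 0.30) and Lck (0.59, SE 0.19) rose adjusted over the list alone, and 0 over all genes (camera adjusted p = 0.00392, adjusted p = 0.191 with an estimated correlation). Cd4, which rose in poly(GR) as well (0.34, SE 0.07) adjusted over the list alone, is also expressed by microglia. Ddit3, which encodes the stress transcription factor CHOP, rose (0.72, SE 0.16) as 1 of 26 genes of the unfolded protein and integrated stress response list, adjusted over the list alone, and 0 rose over all genes. The list was not called (camera adjusted p = 0.681). Ribosomal protein genes had log2 fold changes above 0 in 53 of 53 cases, with 0 called adjusted over the list alone and 0 over all genes (camera adjusted p = 3.41e-06, adjusted p = 0.694 with an estimated correlation), and the list pointed down with 1 surrogate variable. In poly(GR) 51 of 53 had log2 fold changes below 0 (camera adjusted p = 4.2e-08, adjusted p = 0.527 with an estimated correlation).

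In the deep-layer cortex list, Tshz2 fell in both cohorts adjusted over the list alone, by -0.58 (SE 0.12) in poly(PR) and -0.41 (SE 0.11) in poly(GR), and Syt6 rose in both, by 0.33 (SE 0.12) and 0.28 (SE 0.06). Of its 12 genes 1 was higher and 4 lower in poly(PR), and 1 higher and 3 lower in poly(GR), adjusted over the list alone, with 0 over all genes. The list was called in neither (camera adjusted p = 0.278 and 0.329). In poly(GR), 5 of 15 homeostatic astrocyte genes rose adjusted over the list alone and 0 over all genes, including the connexin gene Gja1 (0.28, SE 0.05) and the glutamate transporter gene Slc1a3 (0.29, SE 0.08) (camera adjusted p = 0.000105, adjusted p = 0.527 with an estimated correlation). The proliferation genes Mki67 (-0.48, SE 0.14) and Top2a (-0.71, SE 0.20) fell in poly(GR) as 2 of 20 adjusted over the list alone, with 0 over all genes (camera adjusted p = 0.00841, adjusted p = 0.494 with an estimated correlation).

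The effect of treatment was tested for a difference between the sexes with edgeR. In the poly(PR) cohort 0 of 19156 genes differed (218 at an unadjusted p under 0.05; no other tool was run), a test that rests on control 2, the 1 male control. In the poly(GR) cohort 33 of 18511 did (1797 at an unadjusted p under 0.05), among them the immediate early genes Fos, Arc, Npas4, Junb and Btg2, beside Ttr, Malat1 and several small noncoding RNA genes, named after their values were seen. That count rests on poly(GR) replicate 4, the 1 male of its group, and on the female controls 1 and 2, whose rRNA shares of repeat counts were 59.5% and 49.1% against 22.9% and 25.4% in the male controls. Among female libraries Xist was at 1075 CPM in poly(PR) control 3, 988 CPM in poly(PR) replicate 6, and 926 and 934 CPM in poly(GR) controls 1 and 2, against 523 to 673 CPM in the others.

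Other splits of the same libraries into groups of the same sizes were counted, the real one included. For genes in poly(PR), 2 of 100 splits gave 11 or more, which met the bound of 1 in 20. As 96 of the 100 called no gene, almost any count would have met it. The count in poly(PR) is therefore not read as excluding chance. The highest other split, poly(PR) replicates 1, 2, 4 and 5 against the other 7 libraries, called 2159. A count so far above the real one points to a structure of the samples, and as these 4 are all poly(PR) libraries, the split does not separate that structure from the treatment. Across genes, which are not independent replicates, log2 CPM of controls 2 and 3 correlated with poly(PR) replicate 6 at r = 0.998 and with replicate 5 at 0.991. Replicate 6 correlated with poly(PR) replicates 2 and 7 at 0.998 and 0.999, and control 1 correlated with control 4 at 0.998 and with controls 2 and 3 at 0.996. Control 4 correlated with poly(PR) replicates 1, 4 and 5 at 0.9975, 0.9973 and 0.9977, above its 0.9944 and 0.9946 with controls 2 and 3. The mitochondrial share of gene counts was 4.76% to 6.34% in controls 1 and 4 and replicates 1, 4 and 5, and 3.72% to 4.15% in the rest of the cohort. This likeness thus ran across the groups. What sets these libraries apart was not tested. For genes in poly(GR), 1 of 35 splits gave 32 or more (highest other 14), so chance is excluded there. For shared calls 1 of 100 gave 1 or more (highest other 0), but 96 of the 100 poly(PR) splits and 28 of the 35 poly(GR) splits called no gene, so this count had little room and is not read as excluding chance. For the correlation across genes 1 of 100 pairs of splits gave 0.323 or more (highest other 0.322), which met the bound of 1 in 20. Correlations below 0 were not counted by their size, although the direction of the other splits is arbitrary. With so narrow a margin this count is not read as excluding chance. Chance is not excluded for the lists. In poly(PR) 12 of 100 splits gave 23 or more (median other 13, highest other 29). In poly(GR) 11 of 35 gave 20 or more (median other 17, highest other 27). For the lists of the difference 1 of 60 gave 26 (median other 12, highest other 24), which met the bound of 1 in 20. The margin was narrow here too, and camera called 0 of these lists with an estimated correlation. This count is not read as excluding chance either. With 0 calls in the real split, 60 of 60 splits gave as many genes for the difference (highest other 2). So did 100 of 100, 35 of 35 and 60 of 60 for repeat subfamilies in poly(PR), in poly(GR) and for the difference (highest other 148, 396 and 381).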
